A study of Mus musculus with 6 samples.

How the data were processed

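RNA of inguinal white adipose tissue, the subcutaneous fat depot of the groin in which beige adipocytes form in the cold, was measured in 3 wild-type (WT) and 3 Naa10-knockout (Naa10-KO) male mice, with 1 array per mouse. Naa10 is the catalytic subunit of an N-terminal acetyltransferase. Per the labels' protocols, the mice ate a diet with 60% of its calories from fat from the age of 6 weeks for 15 weeks and stood at 4 °C for 4 h before the fat was taken. Tissue was homogenised in TRIzol, lipid was removed, RNA was purified on RNeasy Plus columns, and 3 µg of total RNA was labelled with biotin and hybridised to the Affymetrix Mouse Genome 430 2.0 array.

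The authors deposited 1 log2 signal for each of 45101 probe sets on each array. On the linear scale, the mean signal after trimming 2% at each end was 500 on all 6 arrays, so the deposited values carry a global scaling of each array to 1 level. The software behind them is not given in the sources used here. Array medians lay between 5.78 and 5.96 on the log2 scale, and the values were used as deposited, with no further normalization and no filter on low values. No detection calls were used, so whether a low probe set lay above background is unknown. The median of all probe set values, 5.85, serves as a mark for low signal.

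Probe sets were named through a GEO platform annotation of 2016. Of 45037 probe sets other than the 64 controls, 34945 had 1 gene, 932 had several genes and 9160 had none in that annotation. The Entrez identifiers of 34741 of the first kind matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Probe sets with several genes or none entered no test of genes. Each of the 18193 genes was represented by its probe set with the highest mean over the 6 arrays. Naa10 was not analysed here, because no probe set carried its name in the annotation used, and the genotype labels were therefore not checked against the targeted transcript.

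Naa10-KO and WT arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, 2-sided). Adjusted p-values are Benjamini-Hochberg values over all genes, with a threshold of 0.05. Differences are Naa10-KO minus WT on the log2 scale, with limma's moderated standard error (SE). Means are given ± SD over n = 3 arrays. The number of arrays limits the precision, and limma borrowed 1.39 prior degrees of freedom per gene.

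Before the data were examined, 32 gene lists were fixed, 20 of pathways and 12 of cell type markers. Of their 716 entries, 661 were measured. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. Member counts are given over all genes and, in those words, adjusted over the list alone.

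The genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean reaches the median of all probe sets. A direction with fewer than 12 is filled to 8 by the smallest unadjusted p and given as values only. Added to these are Ppargc1a, Ucp1, Cidea, Dio2, Prdm16, Elovl3, Cox7a1 and Cox8b by name, and up to 4 members of each list with the smallest unadjusted p. Any other gene named was chosen after its values were seen.

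The labels number the arrays of each genotype 1 to 3. The mice are different animals, and no label ties the numbers to a litter or a day, so genotype alone was fitted.

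The steps were tested on simulated data of 18193 genes on 3 against 3 arrays, 200 of them changed, in 20 simulations. The test recovered 12.4% of genes changed by 1 log2 unit, 47.2% at 2, 63.0% at 3 and 72.3% at 4, with 8.0 false calls per simulation. A list of 30 genes shifted by 1 log2 unit was called in 20 of 20 simulations, and unshifted lists had an unadjusted p under 0.05 in 2.0% of cases. Simulated genes varied independently of each other, so these list rates do not carry over to lists whose genes move together. Estimated correlations between genes in the measured data were 0.09 for the thermogenic list, 0.26 for the extracellular matrix list and 0.50 for the skeletal muscle list.

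Alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, a filter on low values, the mean of all probe sets of a gene, probe sets ending in x_at or s_at left out, eBayes with trend and robust options, array weights, the replicate number as a block, each array left out in turn, all probe sets tested one by one, other thresholds, an unmoderated test per gene with equal variances, other list tests and other memberships of the thermogenic list. A floor at the median of all probe sets, the mean of the skeletal muscle list as a covariate, a fit without WT replicate 3 and Naa10-KO replicate 1, and an estimated correlation and fry on the thermogenic list without muscle-shared members were chosen after seeing the data.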

Results

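Gene expression in inguinal white fat was compared between WT and Naa10-KO mice on a high-fat diet after 4 h at 4 °C, with 3 arrays of each genotype. The series title gives the question as whether Naa10 restrains thermogenesis by beige adipocytes. It names Pgc1α, the coactivator encoded by Ppargc1a, as the proposed target. The arrays measured RNA only, so the Pgc1α protein and its modification were not measured. Correlations between pairs of arrays lay between 0.903 and 0.917 over all probe sets, so no array was a copy of another.

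Of 18193 genes, 16 were higher and 5 were lower in Naa10-KO than in WT fat in limma at an adjusted p of 0.05. The largest rise was that of Asb5, a substrate adaptor of ubiquitin ligases, from 5.91 ± 0.93 in WT to 12.06 ± 0.30 in Naa10-KO (log2 difference 6.15, SE 0.50, adjusted p = 0.0428). Fabp3, a cytosolic fatty acid carrier of heart, muscle and brown fat, rose from 6.16 ± 0.31 to 11.21 ± 0.32, a 33.1-fold difference (log2 difference 5.05, SE 0.25, adjusted p = 0.0270). A second Fabp3 probe set, not used for the gene, was at 6.02 in WT and 5.88 in Naa10-KO (log2 difference -0.14). Pvalb, the calcium buffer parvalbumin, rose 15.1-fold, and Ampd1, the muscle isoform of AMP deaminase, rose 13.2-fold. Other rises were those of Rpl3l (11.4-fold), a ribosomal protein of heart and skeletal muscle, Tpm1 (8.47-fold), a tropomyosin, Ctxn3 (8.03-fold), Ttll7 (7.01-fold), a tubulin polyglutamylase, and Srl (5.18-fold), a calcium-binding protein of the sarcoplasmic reticulum. Tuba4a, an α-tubulin, rose 4.46-fold, Ldb3, a protein of the muscle Z-disc, rose 4.24-fold, and Rtn4r, a receptor of myelin inhibitors, rose 4.12-fold. Adjusted p-values of these 12 genes lay between 0.0270 and 0.0482, and in each of them all 3 Naa10-KO arrays lay above all 3 WT arrays. WT arrays of Ampd1, Rpl3l, Ctxn3, Ttll7 and Rtn4r all lay below the median of all probe sets, so their folds depend on signals near the low end. With low values raised to that median, the folds were 8.39 for Ampd1, 3.86 for Rpl3l, 3.89 for Ctxn3, 5.29 for Ttll7 and 1.07 for Rtn4r. The other 4 risers, which the naming rule left out, were Phka1 (log2 difference 1.93), a muscle subunit of phosphorylase kinase, and Fzd9, Stfa2l1 and Cst10, whose means lay below the median of all probe sets in both genotypes.

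Among the 5 genes that fell, Nos1ap, an adaptor of neuronal nitric oxide synthase, went from 5.98 ± 0.14 in WT to 2.86 ± 0.33 in Naa10-KO (log2 difference -3.12, SE 0.21, adjusted p = 0.0408). Its WT mean was close to the median of all probe sets, and with low values raised to that median the difference was -0.14. Pex5l, a relative of the peroxisomal import receptor, fell from 8.15 ± 0.09 to 6.22 ± 0.20 (log2 difference -1.92, SE 0.16, adjusted p = 0.0460). The other 3 fallers, Plekha6, Stra6l and Ccdc25, lay below that median in both genotypes. Values of the next genes by rank that did not pass were -3.05 for Tmem229a (adjusted p = 0.0736), -1.67 for Plppr4, -1.28 for Klra7, -1.02 for Rps4l, -1.06 for Rbm28 and -0.87 for Dkk3. With the low values raised, those of Tmem229a and Klra7 were -0.27 and -0.22.

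Groups of 3 arrays did not overlap in 18.1% of genes, against 10% by chance, with 1821 genes higher and 1481 lower in all Naa10-KO arrays. With 1 array left out, the differences of the 21 genes kept their sign in 6 of 6 fits, with Asb5 between 5.82 and 6.68 and Tpm1 between 2.94 and 3.24. Calls in limma were 0 in each direction without any 1 of the arrays other than WT replicate 3, with 1220 to 1716 genes at an unadjusted p under 0.05 in those 5 fits. In those fits the influence of an array was not separated from the loss of a degree of freedom. Without WT replicate 3, with the same loss, 29 genes were higher and 1 was lower. Of these 29, 10 were on the skeletal muscle list, against 1 of the 16 with all arrays, and 5 of the 21 calls were shared.

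The thermogenic list, genes of the brown and beige adipocyte programme that burns fuel for heat, rose as a group in Naa10-KO fat (31 measured, median log2 difference 0.49, camera adjusted p = 8.87e-06). The call did not hold with an estimated correlation (adjusted p = 0.421) or in fry (adjusted p = 0.0637). Without Naa10-KO replicate 2 the median was 0.32 (adjusted p = 0.00153, within a range of 5.00e-08 to 0.571 over all alternatives). Skeletal muscle markers moved on the same arrays, with list means of 9.55 to 9.83 on the Naa10-KO arrays and 4.45 to 7.28 on the WT arrays. Over all genes 1 thermogenic member rose (Fabp3), 0 fell and 30 did not pass, and 8 rose when adjusted over the list alone. Risers over all genes numbered 4 with the filter on low values (Fabp3, Cox7a1, Ckmt2 and Ucp1) and 5 with the floor (these and Cidea). With trend and robust options they numbered 7 (these, Cidea, Cox8b and Slc27a2). The 8 that rose when adjusted over the list alone were these 7 and Letmd1. Among them, Fabp3, Cox7a1, Cox8b and Ckmt2 are also strongly expressed by skeletal muscle. Means were higher in Naa10-KO for 24 of the 31, and for 12 of them all 3 Naa10-KO arrays lay above all 3 WT arrays.

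Ucp1, the uncoupling protein of brown and beige mitochondria, was at 3.79 ± 1.09 in WT and 9.95 ± 0.69 in Naa10-KO, a log2 difference of 6.17 (SE 0.65, 71.8-fold). Its adjusted p of 0.0713 did not pass over all genes, although all 3 Naa10-KO arrays lay above all 3 WT arrays. All WT arrays of Ucp1 lay below the median of all probe sets, and with low values raised to that median the difference was 4.10. Adjusted p-values of Ucp1 ranged from 1.20e-04 to 0.312 over the alternatives, and it passed with the filter on low values (0.00505), with trend and robust options (1.20e-04) and with the floor (4.59e-04). Cidea, a lipid droplet protein abundant in brown fat, was at 9.44 ± 0.55 in WT and 11.54 ± 0.66 in Naa10-KO, a 4.30-fold difference that did not pass (adjusted p = 0.318). Slc27a2, a fatty acid transporter and acyl-CoA synthetase, was at 2.13 ± 0.87 and 7.63 ± 0.91 (adjusted p = 0.0954), and as its WT arrays all lay below the median of all probe sets, its log2 difference of 5.50 became 1.78 with low values raised to it. The cytochrome oxidase subunits Cox7a1 and Cox8b differed by 2.00 (3.99-fold, adjusted p = 0.0582) and 1.17 (2.25-fold, adjusted p = 0.368) on the log2 scale. With trend and robust options, Cidea (adjusted p = 0.0424), Slc27a2 (0.00254), Cox7a1 (1.20e-04) and Cox8b (0.0143) passed over all genes. Cidea (0.0417) and Cox7a1 (8.68e-04) also passed with the floor, and Cox7a1 with the filter on low values (0.00461). None of these genes passed in the alternatives that called 0 genes. Adjusted over the list alone, Ucp1, Cidea, Slc27a2, Cox7a1 and Cox8b all passed.

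Other regulators and markers of beige fat did not pass. Ppargc1a was at 7.08 ± 0.49 in WT and 7.35 ± 0.38 in Naa10-KO (log2 difference 0.27, SE 0.33, adjusted p = 0.809). That value came from a probe set ending in x_at, which had the smallest difference of the gene's 5 probe sets. The largest was 0.87 (SE 0.36, limma adjusted p = 0.681 over all probe sets), and all 5 means were higher in Naa10-KO. As RNA levels, these values do not test a change of the Pgc1α protein. Prdm16, a transcriptional regulator of brown and beige fat identity, differed by -0.12 (SE 0.22, adjusted p = 0.873), and its other probe sets by -0.31 to 0.56. Elovl3, a fatty acid elongase induced by cold, differed by 0.36 (SE 0.63), and Dio2, the deiodinase that makes active thyroid hormone, by -0.97 (SE 0.73) at low signal, with its 2 other probe sets at 0.03 and 0.29.

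Skeletal muscle genes moved with genotype over the same arrays. The muscle list had the largest shift of the 32 lists (28 measured, median log2 difference 4.10, camera adjusted p = 1.85e-23). Its call did not hold with an estimated correlation (adjusted p = 0.421) or in fry (adjusted p = 0.0637). Over all genes 1 member rose (Pvalb), 0 fell and 27 did not pass, and 23 rose when adjusted over the list alone. This count depended on the setting. Over all genes, 20 of the 24 members then tested rose with the floor, 9 with the filter on low values and 9 with trend and robust options. Means were higher in Naa10-KO for 26 of 28 members, and 23 had all 3 Naa10-KO arrays above all 3 WT arrays. Myl1, a myosin light chain, was at 11.64 ± 0.50 and 14.72 ± 0.08 (adjusted p = 0.0530). Pygm, the muscle glycogen phosphorylase, was at 5.33 ± 0.63 and 9.03 ± 0.37, and Casq1, the calcium store protein calsequestrin, at 6.36 ± 0.52 and 9.24 ± 0.39. Isoforms of slow fibres, picked after their values were seen, were low in both genotypes, with Myh7 at 3.71 in WT and 3.59 in Naa10-KO, Tnnt1 at 2.90 and 2.80, and Tnni1 at 2.52 and 2.59. Mean log2 signals of the list were 4.45, 5.11 and 7.28 on WT replicates 1 to 3 and 9.78, 9.55 and 9.83 on the Naa10-KO arrays.

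**Figure D1:**
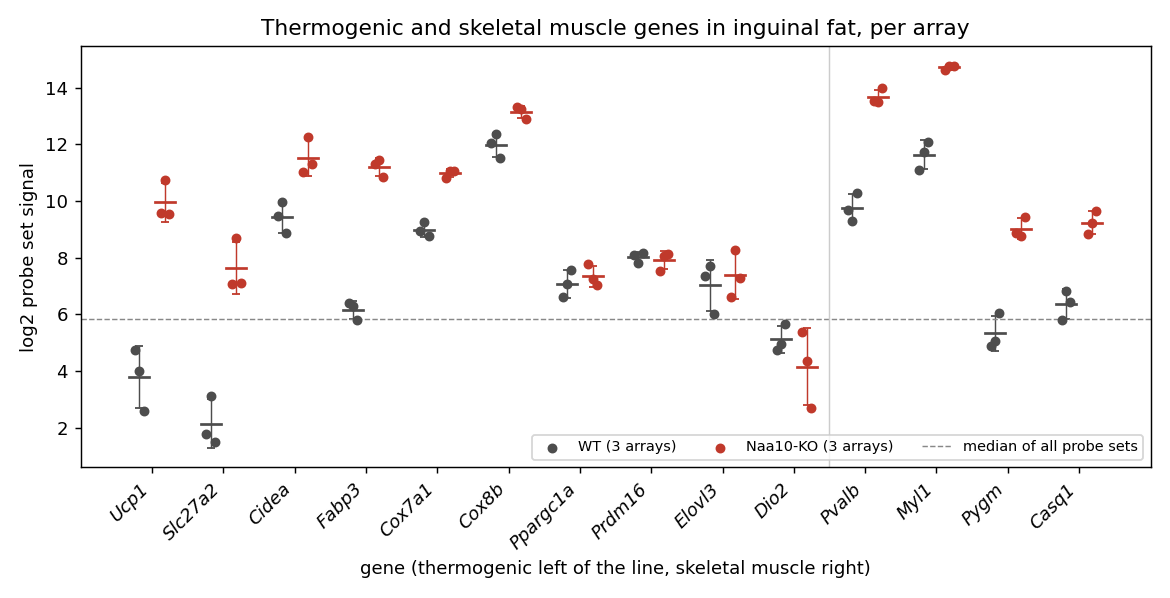
Log2 probe set signal (vertical axis) of 10 thermogenic and 4 skeletal muscle genes (horizontal axis) on each of 3 WT and 3 Naa10-KO arrays, with points for arrays, short lines for means and bars for SD. Ucp1 means were 3.79 in WT and 9.95 in Naa10-KO, those of Ppargc1a were 7.08 and 7.35, and the dashed line marks the median of all probe sets, 5.85.

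Of the thermogenic list, 7 measured members are also strongly expressed by skeletal muscle, among them Fabp3, Cox7a1, Cox8b and Ckmt2, the mitochondrial creatine kinase of striated muscle. Without these 7, the remaining 24 members had a median log2 difference of 0.40 and a camera adjusted p of 0.0155, which did not hold with an estimated correlation (adjusted p = 0.571) or in fry (adjusted p = 0.160). With the mean of the muscle list as a covariate, the full thermogenic list kept a positive median of 0.32 but did not pass (adjusted p = 0.0609). Ucp1 differed by 9.33 in that limma fit (adjusted p = 0.309), against 6.17 without the covariate. Muscle list means did not overlap between genotypes, and WT replicate 3 alone held 62.7% of their variation within groups. The fit thus rests largely on that array and cannot separate muscle signal from genotype.

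Genes of the extracellular matrix fell as a group in Naa10-KO fat (27 measured, median log2 difference -0.44, camera adjusted p = 2.47e-04), a call that did not hold with an estimated correlation (adjusted p = 0.571) or in fry (adjusted p = 0.274). Without Naa10-KO replicate 1 the matrix median was -0.28 (adjusted p = 0.00200). No single member passed, over all genes or adjusted over the list alone, while means were lower for 23 of 27. Postn, the matrix protein periostin, was at 12.26 ± 0.25 in WT and 11.63 ± 0.10 in Naa10-KO, and the collagen chains Col5a1, Col5a2 and Col4a2 differed by -0.61, -0.84 and -0.87. Cholesterol synthesis genes fell as a group as well (19 measured, median -0.35, adjusted p = 0.00358), with 15 means lower and 0 members past the threshold. With an estimated correlation this call was lost (adjusted p = 0.423), as in fry (adjusted p = 0.245). Farnesyl diphosphate synthase, Fdps, differed by -1.27, Nsdhl by -1.10 and Dhcr7 by -0.82, whereas Stard4, a cholesterol carrier, differed by 0.58. Inflammatory cytokines and acute-phase genes fell as a group (21 measured, median -0.46, adjusted p = 0.0155), with 15 means lower and 0 members past the threshold. That call too was lost with an estimated correlation (adjusted p = 0.421) and in fry (adjusted p = 0.114). Saa3, an acute-phase protein, differed by -1.76, and the neutrophil protein S100a8 by -1.38. Lcn2 and Tnf differed by -1.11 and -2.56, but all 6 arrays of both lay below the median of all probe sets, and with low values raised to it both differences were 0. With the mean of the muscle list as a covariate, which follows genotype and cannot be separated from it here, none of the 3 lists passed. The matrix median was then -0.62 (adjusted p = 0.441) and the cytokine median -0.38 (0.892), both still negative, while the cholesterol median turned to 0.14 (0.892). The cytokine call was also lost without WT replicate 1 (adjusted p = 0.0901), without Naa10-KO replicate 3 (0.156), with the filter on low values (0.0854) and with the floor (0.130), and the cholesterol call without WT replicate 1 (0.0546). Over all alternatives, adjusted p-values ranged from 1.72e-05 to 0.571 for the matrix list, from 3.61e-04 to 0.892 for cholesterol synthesis and from 0.00244 to 0.892 for cytokines. Muscle list means were 9.55 to 9.83 on the Naa10-KO arrays and 4.45 to 7.28 on the WT arrays, and control probe sets for Gapdh on Naa10-KO replicate 1 had a 3' minus 5' log2 signal of 0.55 against -0.27 to 0.01 on the other arrays.

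Lists of fuel use did not pass. Oxidative phosphorylation had 49 of 71 means higher (median 0.10, adjusted p = 0.10), with Atp5g1 at 0.50, Ndufs7 at 0.36 and Ndufb7 at -0.38. Fatty acid oxidation had a median of 0.02 (26 measured, adjusted p = 0.840), with Ehhadh, a peroxisomal enzyme of the pathway, at 1.06 (adjusted p = 0.216) and past the threshold when adjusted over the list alone. Creatine and calcium cycling had a median of 0.37 (14 measured, adjusted p = 0.220), and 4 members passed adjusted over the list alone: Ckmt2 (6.02), Atp2a1 (4.56), Ryr1 (1.81) and Gatm (0.61), of which Atp2a1 and Ryr1 are also on the muscle list and Ckmt2 is expressed by muscle. With low values raised to the median of all probe sets, the differences of Ckmt2 and Atp2a1 were 4.74 and 3.92, and the median of the list, over the 11 members then tested, turned to -0.04. Regulators of mitochondrial biogenesis had a median of 0.16 (20 measured, adjusted p = 0.456). De novo lipogenesis had a median of -0.15 (20 measured, adjusted p = 0.0836), with fatty acid synthase, Fasn, at 11.44 ± 0.16 in WT and 10.02 ± 0.42 in Naa10-KO (adjusted p = 0.231) and Scd2, a desaturase, at -1.89. Fasn passed when adjusted over the list alone. The lipogenesis list passed with the mean of all probe sets of a gene (adjusted p = 0.0294) and without x_at and s_at probe sets (0.0284), within a range of 0.0284 to 0.492 over its alternatives. Its median was -0.10 without WT replicate 2 and -0.31 with the muscle covariate. Triglyceride synthesis and lipolysis had a median of -0.02 (22 measured, adjusted p = 0.664), with Mgll at -0.61 and Pck1 at 0.65.

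**Figure D2:**
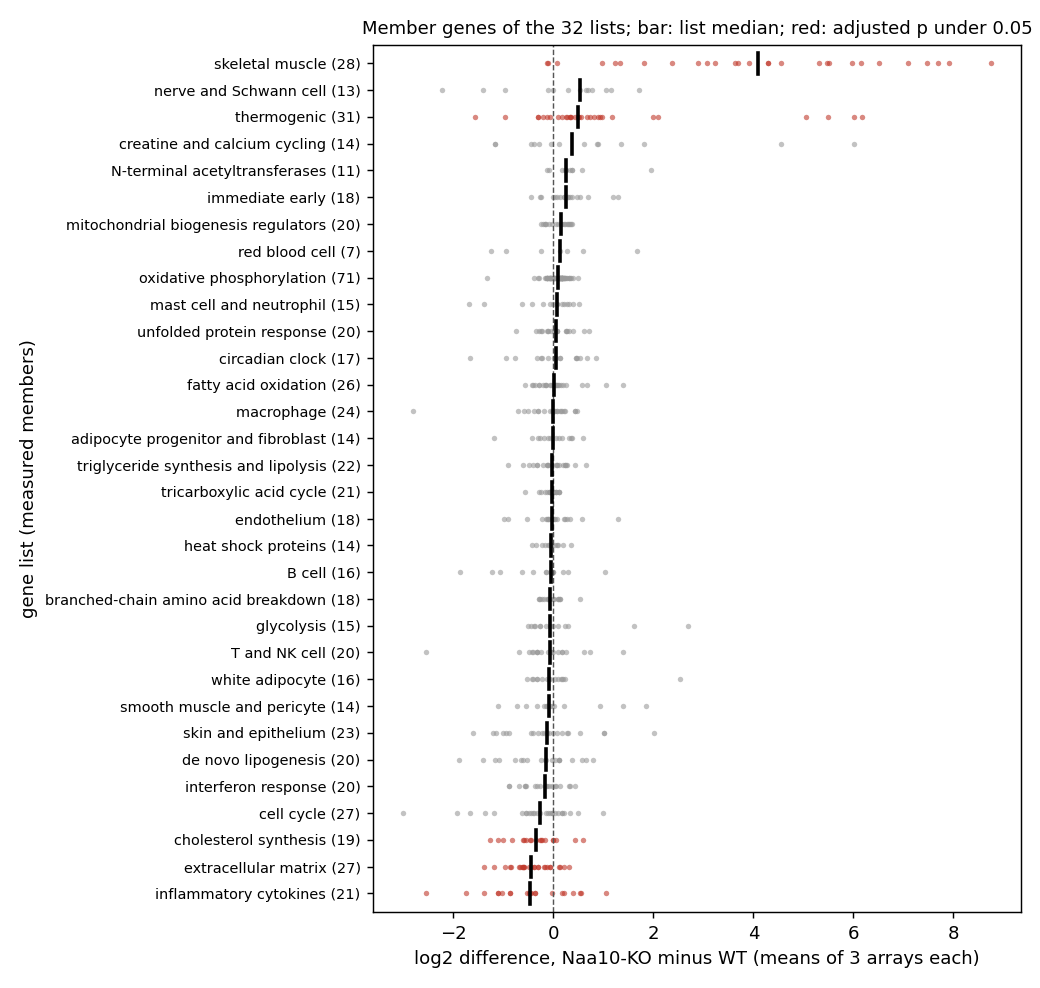
Log2 difference of each member gene, Naa10-KO minus WT, means of 3 arrays each (horizontal axis), for the 32 gene lists with their number of measured members (vertical axis). Points are genes, black bars list medians, and red marks the 5 lists past the camera threshold, from a median of 4.10 for skeletal muscle to -0.46 for inflammatory cytokines.

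Markers of the other cell types that inguinal fat can hold did not pass as groups. Adjusted p-values were 0.644 for white adipocytes (16 measured, median -0.08), 0.723 for progenitors and fibroblasts (14, median -9.92e-04), 0.664 for macrophages (24, median 4.92e-04), 0.827 for endothelium (18, median -0.04) and 0.609 for smooth muscle and pericytes (14, median -0.09). They were 0.609 for T and NK cells (20, median -0.08), 0.456 for B cells (16, median -0.06), 0.700 for mast cells and neutrophils (15, median 0.06), 0.700 for skin and epithelium (23, median -0.12), 0.456 for nerve and Schwann cells (13, median 0.53) and 0.723 for red blood cells (7, median 0.12). The B cell list passed, downward, in 4 alternatives, within a range of 0.0107 to 0.928. Among them were the fits without WT replicate 3 (median -0.69, adjusted p = 0.0266) and without Naa10-KO replicate 3 (-0.85, 0.0107). Its direction turned upward without Naa10-KO replicate 2 (median 0.53, adjusted p = 0.609) and with the muscle covariate (1.60, 0.155). B cell list means were 8.13, 7.97 and 6.59 on WT replicates 1 to 3 and 7.45, 5.96 and 8.50 on the Naa10-KO arrays, a wide spread within each genotype. White adipocyte markers passed, downward, with the muscle covariate, which follows genotype (median -0.37, adjusted p = 0.0219, range 0.0219 to 0.914). Their direction turned upward without WT replicate 3 (median 0.11, adjusted p = 0.678) and without both WT replicate 3 and Naa10-KO replicate 1 (0.11, 0.404). Single members of a list went either way. Lep, the leptin gene of white adipocytes, was at 15.02 ± 0.10 in WT and 14.70 ± 0.24 in Naa10-KO. Agt of the same list differed by 2.54 on overlapping arrays, or 0.87 with low values raised to the median of all probe sets. Pdgfra, a marker of adipocyte progenitors, differed by 0.60 and Col1a1 of that list by -1.18. Trem2, of lipid-associated macrophages, differed by -2.80 (adjusted p = 0.377), or -1.04 with low values raised, while 12 of 24 macrophage means were higher. Pecam1 of endothelium differed by 0.33 and Prox1, at low signal, by -0.99. Mylk of smooth muscle differed by -1.11 and Des of that list by 1.40. Among these lists the sign of the median differed from that of the mean for white adipocytes, macrophages, smooth muscle, and mast cells and neutrophils. With low values raised to the median of all probe sets, the medians of progenitors and fibroblasts and of endothelium turned to 0.06 and 0.02, and that of macrophages to -0.0047. Camera's direction was opposite to median and mean for endothelium, red blood cells, and progenitors and fibroblasts.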

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

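Chosen after the results were seen were the tests of a common muscle factor, of genotype on the muscle list, of the muscle covariate on Ucp1, Cidea and Slc27a2, of brown fat markers and of dilution of the matrix genes.

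A control outside the gene comparison stood apart on 1 array. Probe sets at the 3' and 5' ends of Gapdh differed by 0.55 log2 units on Naa10-KO replicate 1, above the WT arrays (-0.17, -0.20 and -0.27) and the other Naa10-KO arrays (0.01 and -0.19). Actin control probe sets differed by 2.07 on the same array and by 1.42 to 1.85 on the others. The ThrX control had a log2 signal of 5.22 on that array. It was at 6.72 and 7.29 on the other Naa10-KO arrays and at 7.67 to 7.86 on the WT arrays. All 3 Naa10-KO arrays thus lay below all 3 WT arrays for this control. The DapX control overlapped between genotypes, at 6.65, 7.54 and 8.36 on Naa10-KO and 7.95 to 8.15 on WT arrays. Whether a processing difference between the genotypes affected the gene values was not tested.

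The first pattern is the rise of skeletal muscle genes in Naa10-KO fat. If fast muscle fibres were carried along with the dissected fat in varying amounts, the 10 list genes with a log2 value above 8 in WT replicate 3 should stand above it by 1 common factor. The SD of these differences over genes was 1.01 (bootstrap interval over genes 0.33 to 1.42), and 0.56 without Acta1. This was left open because the interval spans the bound of 1. An effect of genotype on the muscle genes stays open too, since the list means separated the genotypes by 4.11 log2 units with an exact 2-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. Both explanations cannot be told apart here, and 1 of 10 splits of the arrays, the real one, gave a list median as large (4.10, against 2.21 for the highest other), too few splits to judge chance.

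The second pattern is the rise of thermogenic genes. That the 7 members set aside as muscle-shared were the sole source of the list's camera call is argued against. The 24 other members passed the same camera test (adjusted p = 0.0155, median 0.40 against 0.49). However, neither they (0.571 and 0.160) nor the full list (0.421 and 0.0637) passed with an estimated correlation or in fry. Whether muscle expresses any of the 24 was not checked, and Ucp1 and Slc27a2 entered without a floor. The test therefore does not separate the list's rise from muscle signal. For Ucp1, Cidea and Slc27a2, carried-over muscle stays open as a candidate source: with the muscle list mean as a covariate, their mean genotype coefficient was 6.51 (SE 1.71 over the 3 genes), against 4.59 without it, both with Ucp1 and Slc27a2 low in WT and not raised to any floor, but WT replicate 3 alone held 62.7% of the muscle variation within groups. That array had the highest muscle mean of the WT arrays and the lowest Ucp1 value, 2.60, against a mean of 4.38 on WT replicates 1 and 2. More adipocytes of the classical brown type stay open as well, with Lhx8 at -0.31 and Zic1, at low signal, at 0.97, and 1 of 10 splits, the real one, gave a list p as small (5.55e-07, against 0.00412 for the lowest other), too few to judge chance.

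The third pattern is the lower extracellular matrix list. Lower RNA quality of Naa10-KO replicate 1 could contribute. Without that array the median difference was -0.28 (bootstrap interval over genes -0.33 to -0.13), against -0.44 with all arrays. A bound at 50% of the value with all arrays lay inside the interval, so this stays open. Dilution of the fat by another tissue should lower all markers of resident cells alike. The pooled median of 84 such markers lay 0.41 log2 units above that of the matrix list (bootstrap interval over genes 0.17 to 0.62). The allowed gap of 0.2 lies inside that interval, so the test does not decide. With all their members, the white adipocyte, progenitor, macrophage, endothelium and smooth muscle lists had medians between -0.09 and 4.92e-04, against -0.44 for the matrix list. A lower matrix expression in Naa10-KO fat was not tested apart from RNA quality and dilution.

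The count of genes past the threshold was 21 in the real split of the 6 arrays and at most 0 in the other 9, so that 1 of 10 splits gave as many. For gene lists, 2 of the 10 splits gave as many as the real one, which had 5, and the highest other also had 5. With 10 splits no share under 0.05 can be reached.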

How the results depend on the processing

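The alternatives with a floor, with the muscle list mean as a covariate, without both WT replicate 3 and Naa10-KO replicate 1, and with other list tests on the thermogenic list without muscle-shared members were chosen after seeing the data. The 16 higher and 5 lower genes became 70 and 5 with the filter on low values, 102 and 35 with trend and robust options, 123 and 24 with the floor, 27 and 7 with array weights, 14 and 3 after quantile normalization, 20 and 4 with arrays centred, 40 and 10 at an adjusted p of 0.10, and 245 and 163 at an unadjusted p under 0.01 with 1.5-fold. They became 0 and 0 in limma with the mean of all probe sets of a gene (1491 genes at an unadjusted p under 0.05), with the muscle covariate (1070), without both arrays (1564) and with all probe sets one by one (3362), and also in an unmoderated test per gene with equal variances (1861). With the replicate number as a block, limma called 0 and 0 genes (1276 at an unadjusted p under 0.05); deviations of same-numbered arrays correlated at -0.0067, -0.0057 and -0.031, and the block changed no list call. With 1 array left out, 0 to 29 genes were higher and 0 to 1 lower. All 21 genes kept their sign in 6 of 6 such fits, and Tpm1, Pvalb, Asb5, Fabp3 and Ampd1 kept the call in 1, without WT replicate 3. The filter and the floor each shared 13 of the 21 calls.

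The 2 higher and 3 lower lists became 0 and 0 with an estimated correlation and in fry, and 0 and 1 with the muscle covariate. In the covariate fit the muscle list was adjusted for its own mean, so the loss of its call there is no test of it. Lower lists numbered 5 with the mean of probe sets, with array weights and without both arrays, and 1 to 4 with 1 array left out. The thermogenic list lost its call with an estimated correlation (0.421), fry (0.0637) and the muscle covariate (0.0609), and without muscle-shared members in the first 2 (0.571 and 0.160). So did the skeletal muscle list with an estimated correlation (0.421) and fry (0.0637). Cholesterol synthesis turned upward with the muscle covariate (adjusted p = 0.892). Fewer arrays, fewer genes tested or a covariate that follows genotype are part of some of these settings, and otherwise the cause was not tested. With 1 array left out, adjusted p-values of the thermogenic list were 7.84e-06 to 0.00153 and those of the muscle list 8.13e-33 to 4.01e-17. Over all alternatives, values of single named genes stayed on their side of the threshold in 2263 cases, lost it in 145, gained it in 60 and moved in 45, and 0 called genes reversed. Those of the other lists stayed in 504, lost it in 13, gained it in 18 and moved in 34. Most named genes and most of these lists had not passed to begin with, so most that stayed had no call to lose. With the replicate number as a block, for example, 14 named genes lost the call and 137 stayed. In fry, 3 of the other lists lost the call and 27 stayed. Other pseudocounts were not run, as the values are log2, nor was the Naa10 level. Without detection calls, signal over background limits what low probe sets can show.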

Other observations

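Other pathways that respond to cold, stress or feeding did not pass as lists on the values as deposited over all 6 arrays. Immediate early genes had 14 of 18 means higher in Naa10-KO fat (median log2 difference 0.26, adjusted p = 0.110), with Nr4a1, a nuclear receptor induced by adrenergic signals, at 6.82 ± 0.17 in WT and 8.11 ± 0.41 in Naa10-KO and Nr4a3 at a difference of 1.19, or 0.69 with low values raised to the median of all probe sets. Cell cycle genes had 19 of 27 means lower (median -0.27, adjusted p = 0.144), with Mki67 at -3.01 on overlapping arrays, or -0.71 with low values raised to the median of all probe sets. Interferon response genes had 14 of 20 means lower (median -0.16, adjusted p = 0.0567), with Irf7 at -0.88 and Ifit3 at -0.57. That list passed in 6 alternatives, within a range of 0.00511 to 0.892. Among them were the floor (adjusted p = 0.0388, median -0.21) and the fit without Naa10-KO replicate 1 (0.00511, median -0.31). With the muscle covariate its median was -0.02. Circadian clock genes had a median of 0.04 and a mean of -0.03 (17 measured, adjusted p = 0.664), with Nr1d2 at 0.54 and Cry1 at -0.33. Adjusted p-values were 0.664 for the unfolded protein response (20 measured, median 0.05), with Chac1 at 0.71 and Edem1 at -0.74, and 0.664 for heat shock proteins (14 measured, median -0.05).

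Among metabolic lists, the tricarboxylic acid cycle had a median of -0.03 (21 measured, adjusted p = 0.609), with Dlat at -0.56, and branched-chain amino acid breakdown a median of -0.07 (18 measured, adjusted p = 0.664), with Acad8 at 0.54. Glycolysis had a median of -0.07 and a mean of 0.16 (15 measured, adjusted p = 0.700). Pfkm, the muscle isoform of phosphofructokinase, was at 8.53 ± 0.39 in WT and 10.14 ± 0.18 in Naa10-KO and passed when adjusted over the list alone, while Pfkl, the liver isoform, was at 9.32 ± 0.20 and 8.82 ± 0.15. Muscle list means were 9.55 to 9.83 on the Naa10-KO arrays and 4.45 to 7.28 on the WT arrays. N-terminal acetyltransferases other than Naa10 had 9 of 11 means higher (median 0.26, adjusted p = 0.0541), with Naa50 at 12.77 ± 0.18 and 13.10 ± 0.07, and Hypk, a partner of the Naa10 complex, at 3.35 ± 1.42 and 5.32 ± 0.42, both below the median of all probe sets. The acetyltransferase list passed in 5 alternatives, within a range of 0.0266 to 0.913. Among them were the fits without WT replicate 3 (median 0.43, adjusted p = 0.0266) and without Naa10-KO replicate 3 (0.32, 0.0391). With the muscle covariate the median was -0.03.

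A hypothesis was that alleles of the donor strain, carried along with the targeted locus on the X chromosome, may differ in signal. Of the 40 measured genes nearest to Naa10, 4 had an unadjusted p under 0.05, against 9.20% of all other genes (Fisher's exact test, 1-sided, p = 0.509), so no excess was found, which does not exclude single genes.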
